A study of Mus musculus with 6 samples.

How the data were processed

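RNA was sequenced from 6 samples of Neuro2a, a mouse neuroblastoma line that is often used as a neuron-like model. Per the labels, the cells grew in 6-well plates and received an adenovirus carrying either a control short hairpin RNA (shCtrl, 3 samples) or a hairpin against Fam172a (shFam172a, 3 samples), and were harvested after 48 h. Total RNA was taken with TRIzol, libraries were made with the VAHTS Universal V6 kit, and paired-end reads came from a NovaSeq instrument, per the labels' protocols. Nothing in the labels says whether the 3 samples of a group came from separate infections or days. The p-values below therefore measure only the spread between these samples, which may be technical.

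The deposited values are raw counts per gene symbol, which the authors did not normalize. HISAT2 2.0.5, HTSeq and the mouse build mm10 are named in the submitters' processing notes. The gene annotation behind the counts and the strand setting of the counting are not given in the sources used here. The series table was used for all tests, and the single-sample tables held the same counts. The table also has 5 rows that name no gene, which were left out of library sizes and tests. Their shares of all rows, as the mean over 3 libraries, were 16.5% in shCtrl and 17.4% in shFam172a for pairs in no gene, and 9.64% and 10.3% for pairs with several alignments. Pairs of too low alignment quality made up 5.26% and 6.08%, pairs ambiguous between genes 1.81% and 1.80%, and pairs not aligned 0.825% and 0.991%. Replicate 3 of shFam172a stood apart from replicates 1 and 2. Its pairs of too low alignment quality were 4.46% against 6.65% and 7.12%, and its pairs not aligned 0.780% against 1.10% in both. Its pairs in no gene were 17.9% against 17.2% in both.

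Gene counts summed to 11250312 to 12820531 per library in shCtrl and to 21690467 to 23409319 in shFam172a. Low genes were therefore measured less precisely in shCtrl. Replicates were compared by a chi-square test of their counts over genes with at least 100 counts in a pair. The statistic per degree of freedom was 1.61 to 2.84 for pairs of the same group and 12.6 to 17.4 for pairs of different groups. No pair of libraries therefore agreed within sampling noise, and each library was counted as 1 sample. Among pairs of the same group, those with shFam172a replicate 3 had the highest values, 2.84 and 2.71, and the next highest was 1.96.

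Genes were filtered with filterByExpr by group, which left 12820 of 18128 genes with any count. The counts were scaled by TMM and tested with edgeR 4.0.16 (glmQLFit with robust estimation, then glmQLFTest) in R 4.3.3, with group as the sole term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. A log2 fold change is shFam172a over shCtrl, its SE is its size divided by the square root of the F statistic, and CPM values are depth-scaled counts after TMM, given as mean ± SD with n = 3. Principal components were taken from log2 CPM with a prior count of 2 over the 500 genes of highest variance. On counts simulated from these libraries over 12820 genes, 50 genes were changed at each fold size. The test recovered 35 genes at 1.25-fold, 45 at 1.5-fold, 50 at 2-fold and 50 at 4-fold, and called 11 of 12620 unchanged genes. The changed genes were drawn only from genes with enough expected counts in the smallest library, so the recovery does not cover low genes. Far fewer genes were changed there than were called in the data.

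Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, two-sided and adjusted over the 28 lists with a tested member. Beside it stand an estimated correlation and fry. The 29 lists came from the series title (glycolysis and lactate, histone lactylation and acetylation enzymes, POMC processing and melanocortin-leptin signalling), from responses that a viral hairpin can set off (interferon, NF-kB, the integrated stress response, endoplasmic reticulum chaperones, p53, the small RNA pathway with AGO proteins), and from the state of the line. The last kind held G2 and mitosis, S phase, cholesterol and fatty acid metabolism, the neuronal cytoskeleton and synapse, sympathoadrenal genes, axon guidance, CHD and SWI/SNF remodellers, mitochondrially encoded genes, respiratory chain, ribosomal proteins, hypoxia, NRF2, immediate early genes, extracellular matrix and TGF-beta, and lysosome and autophagy. Markers of fibroblasts, macrophages, astrocytes with oligodendrocytes, and endothelium with epithelium covered other cell types. On simulated counts of the same comparison over 12820 genes, 0 of 20 random lists of 25 unchanged genes passed. A list in which 15 of 25 genes rose 1.25-fold did pass. The simulated genes varied independently, so this does not measure false calls for lists whose genes vary together. In the real data the estimated correlation within a list reached 0.55, for cytosolic ribosomal proteins.

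The samples, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names Fam172a, then Pomc, Ldha, Ldhb, Slc16a1 and Ep300 whatever their result, then the 6 largest rises and 6 largest falls among called genes with a mean CPM of at least 2, no overlap between groups and a symbol that is not a predicted model or clone. It adds the 3 members with the smallest p in the direction of each list past its threshold, and the member with the smallest p of every other list if called. It gives 63 genes, of which a few are not reported here. Other genes are named only where the text says that they were chosen after their values were seen. Alternatives were the RLE and upper quartile scalings, library totals alone, other filters, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out, a stricter threshold, a test against a 1.5-fold change, and for the lists an estimated correlation and fry. A thinning of all libraries to the smallest total, and a loess correction (span 0.5) for transcript length and GC, were added after the data were seen.

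Coordinates, exon overlaps, transcript lengths and 3' UTRs came from the GENCODE annotation of GRCm38, the same assembly as mm10. Of 24421 symbols in the table, 23338 matched a gene by symbol and 667 through a synonym. Symbols of the mitochondrially encoded genes are not among those analysed here, so that list has no result. Of the named genes, Slc7a7, Acss2, Cxcl10, Nusap1, Phox2a, Cnp and Shmt2 share exon sequence with a protein-coding gene on the opposite strand. As the strand setting is not given, whether the counting told reads of such pairs apart is not known. Selenbp1 has the near-identical paralog Selenbp2, and the counts of ribosomal protein and glycolysis genes can be affected by their processed pseudogenes.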

Results

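The data are gene counts from Neuro2a cells 48 h after adenoviral delivery of a control hairpin (shCtrl, n = 3) or a hairpin against Fam172a (shFam172a, n = 3). The series title places Fam172a in histone lactylation, in neurons that make pro-opiomelanocortin, and in energy balance. The comparison asks which transcripts differ when Fam172a is lowered in this line. Gene counts summed to 11632001, 12820531 and 11250312 in the shCtrl libraries and to 21690467, 23409319 and 22287169 in the shFam172a libraries, so the deeper sequencing goes with the knockdown. The first principal component held 48.7% of the variance and separated the groups. The second held 18.8% and spread the shCtrl libraries, which lay between -9.65 and 10.1, while the shFam172a libraries lay between 0.26 and 0.61. Rn45s, the ribosomal RNA precursor and a measure of rRNA carried into the libraries, stood at 492 ± 78.2 CPM in shCtrl and 985 ± 177 CPM in shFam172a (adjusted p = 0.021). It was chosen after its values were seen.

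Fam172a itself fell in every shFam172a library. The gene (ENSMUSG00000064138.14) lies on chromosome 13 at 77702033 to 78166235 of GRCm38, on the plus strand, with 15 merged exons, and shares no exon sequence with another gene. Its counts were 217, 248 and 220 in the shCtrl libraries and 199, 193 and 205 in the deeper shFam172a libraries. In CPM these were 18.6, 19.3 and 19.5 against 9.22, 8.28 and 9.22. The shFam172a mean was 46.5% of the shCtrl mean, a log2 fold change of -1.10 ± 0.092 (SE, adjusted p = 2.4e-12).

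**Figure D1:**
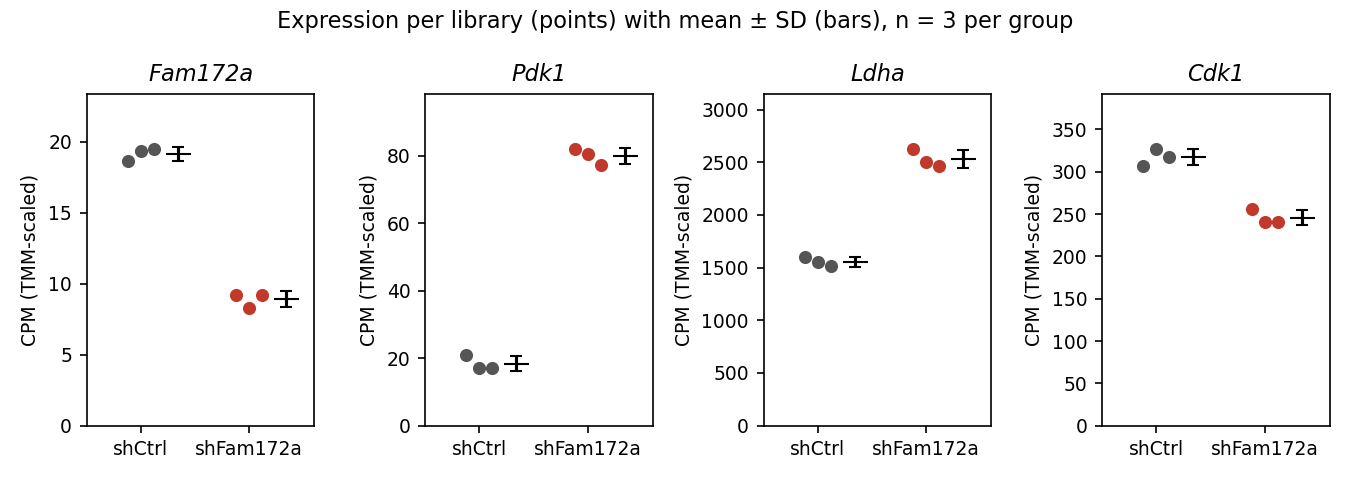
Expression in CPM (linear axes from 0) of Fam172a, Pdk1, Ldha and Cdk1 in each of the 3 shCtrl (grey) and 3 shFam172a (red) libraries; black bars give mean ± SD. Fam172a and Cdk1 lie lower, and Pdk1 and Ldha higher, in all shFam172a libraries than in any shCtrl library.

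Lowering Fam172a went with many small differences and few large ones, and the large ones were mostly rises. Of 12820 genes tested, 2241 were higher and 2386 lower in shFam172a, 36.1% of those tested, with a median absolute log2 fold change of 0.22 among the called genes. At least a 2-fold difference was seen in 100 higher genes and 13 lower genes, and at least a 1.5-fold one in 276 and 74. By the naming rule (mean CPM of at least 2, no overlap, no predicted symbol), the largest rise was that of St3gal1, a sialyltransferase, at a log2 fold change of 2.54 ± 0.23. St3gal1 was low in shCtrl, at 0.960 ± 0.225 CPM with 9 to 13 counts per library. Next were Kbtbd11 at 2.16 ± 0.091 and Pdk1, the kinase that switches off pyruvate dehydrogenase, at 2.12 ± 0.062. Selenbp1 (1.94 ± 0.13), Ndrg1 (1.93 ± 0.082) and the glycogen branching enzyme Gbe1 (1.88 ± 0.14) followed, all with adjusted p of 2.4e-08 or less. Selenbp1 has a near-identical paralog and its value is uncertain.

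The largest fall by the same rule was that of Fam172a. The next were Slc7a7, a cationic amino acid transporter subunit (-0.85 ± 0.21, adjusted p = 0.0014), Frrs1 (-0.79 ± 0.22, adjusted p = 0.0035), Icosl, a ligand of the T cell costimulator ICOS (-0.79 ± 0.12, adjusted p = 1.8e-06), Zfp459 (-0.79 ± 0.24, adjusted p = 0.0081) and Tgfb1 (-0.73 ± 0.14, adjusted p = 1.1e-04). Apart from Icosl and Tgfb1, these had means of 2.68 to 3.39 CPM in shCtrl. Without shCtrl replicate 2, Zfp459 was at -0.56 with adjusted p = 0.14. Tested against a 1.5-fold change, 73 genes were higher and 1 lower, and the lower one was Fam172a. The groups did not overlap for 5891 genes, 46.0% of those tested, where chance gives 10%.

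Genes of glycolysis and lactate handling rose together in shFam172a. Of 22 members tested, 18 rose, 1 fell and 3 did not pass, with a median log2 fold change of 0.77. Slc16a3, the lactate exporter MCT4, went from 452 ± 9.37 to 955 ± 36.4 CPM (1.08 ± 0.029, adjusted p = 4.3e-27). Pdk1 went from 18.4 ± 2.27 to 79.98 ± 2.42 CPM, and Pfkl, the liver-type phosphofructokinase, from 217 ± 5.46 to 428 ± 16.3 CPM (0.98 ± 0.032). Ldha, the lactate dehydrogenase subunit that favours lactate formation, went from 1556 ± 45.1 to 2532 ± 83.9 CPM (0.70 ± 0.027, adjusted p = 8.4e-23). The other monocarboxylate carrier named, Slc16a1, was at 290 ± 3.27 and 295 ± 6.34 CPM (0.02 ± 0.029, adjusted p = 0.57). Ldhb had 0 counts in all 6 libraries, which over their summed gene counts allows up to 0.0291 CPM by counting error alone. Eno1, chosen after its values were seen, was the other member under the filter, at no more than 0.092 CPM in any library. Eno1b, which is not in the list and was also chosen after its values were seen, was higher in shFam172a. Its log2 fold change was 0.73, with adjusted p = 5.2e-04 in the test against a 1.5-fold change. The low Eno1 count is therefore no measure of enolase expression. Whether reads of Eno1 were counted under Eno1b, or the annotation or multiple alignments kept reads from Eno1 and Ldhb, was not tested. The member that fell, chosen after its values were seen, was Pfkfb3 (-0.15). The camera test gave adjusted p = 2.4e-118 at the preset correlation and adjusted p = 0.020 with an estimated correlation, and 18 rose and 1 fell when adjusted over the list alone.

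Targets of hypoxia-inducible factor (HIF), the transcription factor of the low-oxygen response, rose as a group. Of 19 members tested, 18 rose, 0 fell and 1 did not pass, with a median log2 fold change of 1.02. The counts adjusted over the list alone were also 18 and 0. Plod2, a collagen lysyl hydroxylase, went from 122 ± 2.89 to 263 ± 3.03 CPM (1.11 ± 0.032), P4ha2, a collagen prolyl hydroxylase, from 108 ± 6.16 to 254 ± 7.52 CPM (1.23 ± 0.037), and Egln1, the oxygen sensor that marks HIF for degradation, from 157 ± 4.71 to 317 ± 2.45 CPM (1.02 ± 0.031). Their adjusted p values were 3.5e-26, 4.8e-26 and 1.3e-25. The list shared 0 genes with the glycolysis list, which reflects how the lists were drawn up and does not make their rises independent. The camera test of the hypoxia list gave adjusted p = 4.2e-113, and adjusted p = 0.020 with an estimated correlation. The mean log2 CPM of the list was 5.74, 5.50 and 5.59 in the shCtrl libraries and 6.63, 6.61 and 6.57 in the shFam172a libraries, which were also the deeper libraries and those with more Rn45s.

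**Figure D2:**
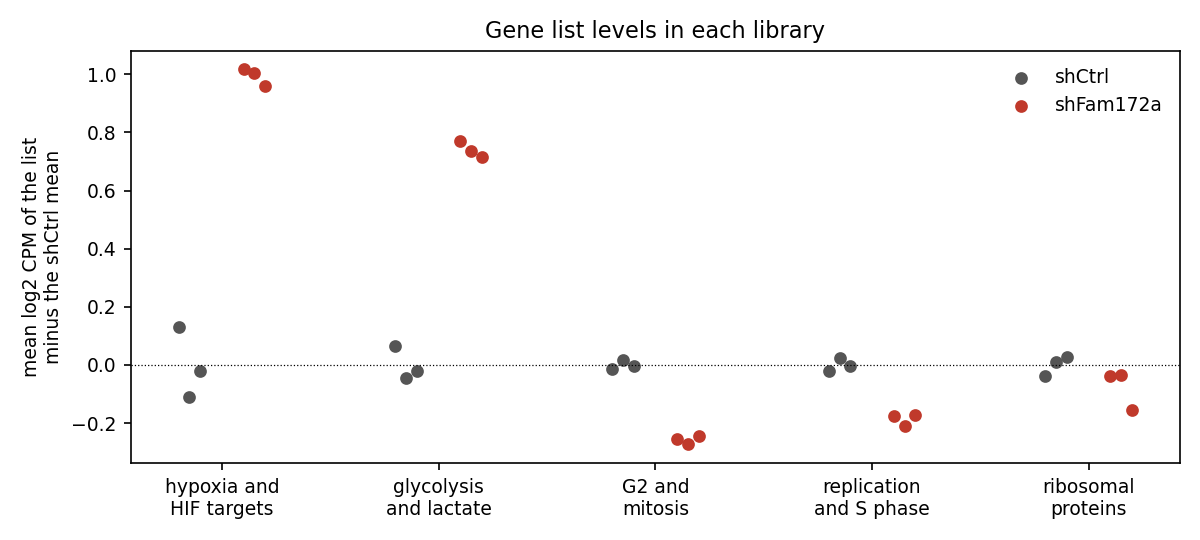
Mean log2 CPM of 5 gene lists in each library, minus the mean of the shCtrl libraries (grey, shCtrl; red, shFam172a; 3 libraries each). The hypoxia list lies 0.99 and the glycolysis list 0.74 higher in shFam172a on average, both cell cycle lists lie lower, and the ribosomal protein list overlaps between the groups.

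Cell cycle genes were lower in shFam172a. In the G2 and mitosis list, 24 of 25 members fell, 0 rose and 1 did not pass, with a median log2 fold change of -0.27. Cdk1, the mitotic kinase, was at -0.37 ± 0.031, Top2a, topoisomerase II alpha, at -0.30 ± 0.025, and Nusap1, a spindle protein, at -0.50 ± 0.043. In the S-phase list, 17 of 30 fell, 1 rose and 12 did not pass, with a median of -0.19. Rrm2, a subunit of ribonucleotide reductase, was at -0.67 ± 0.039 and the primase subunit Prim1 at -0.54 ± 0.040. Adjusted over the list alone, 24 fell in the first list and 22 in the second. The tests gave adjusted p = 3.2e-17 and adjusted p = 3.9e-09 at the preset correlation, but adjusted p = 0.060 and adjusted p = 0.16 with an estimated correlation, so these list calls are lost there. Nusap1 shares exon sequence with Oip5 on the opposite strand.

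Nuclear-encoded respiratory chain subunits and cytosolic ribosomal proteins were lower by small amounts. Of 36 respiratory chain genes, 23 fell, 1 rose and 12 did not pass (median log2 fold change -0.12, adjusted p = 8.0e-06, and adjusted p = 0.57 with an estimated correlation), among them Atp5o at -0.24 ± 0.030, Sdhb at -0.23 ± 0.029 and Cox5a at -0.27 ± 0.039. Of 43 ribosomal protein genes, 18 fell, 1 rose and 24 did not pass (median -0.085, adjusted p = 0.0015, and adjusted p = 0.67 with an estimated correlation), with Rpl14 at -0.26 ± 0.028 and Rps2 at -0.19 ± 0.025. When adjusted over the list alone, 24 and 18 fell. The ribosomal call ended without shFam172a replicate 3 (adjusted p = 0.090), and after a correction for transcript length and GC its median was 0.022 with adjusted p = 0.82, while the respiratory chain median was -0.043 with adjusted p = 0.035.

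Chaperones of the endoplasmic reticulum rose, and genes of the integrated stress response, which adjusts amino acid supply and translation, mostly fell. Of 22 chaperone and unfolded protein response genes, 14 rose, 2 fell and 6 did not pass (median 0.15, adjusted p = 1.7e-04, and adjusted p = 0.16 with an estimated correlation). Hspa5, the chaperone BiP, went from 875 ± 6.77 to 1153 ± 9.94 CPM (0.40 ± 0.025), with Hsp90b1 at 0.25 ± 0.025 and Hyou1 at 0.28 ± 0.027. Of 24 integrated stress response genes, 14 fell, 3 rose and 7 did not pass (median -0.13, adjusted p = 0.011, and adjusted p = 0.57 with an estimated correlation). Mthfd2 and Shmt2, enzymes of mitochondrial one-carbon metabolism, were at -0.33 ± 0.029 and -0.31 ± 0.032, and the secreted factor Gdf15 was at -0.60 ± 0.060. Counts adjusted over the list alone were 14 and 2 for the first list and 3 and 14 for the second. Without shFam172a replicate 3 the stress response list had adjusted p = 0.073.

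Neural genes of the line also differed. Sympathoadrenal transcription factors and catecholamine genes rose in 9 of 16 tested and fell in 0 (median 0.12, adjusted p = 0.0033, and adjusted p = 0.16 with an estimated correlation). Th, the rate-limiting enzyme of catecholamine synthesis, went from 9.28 ± 1.30 to 18.7 ± 1.05 CPM, a 2.01-fold difference (adjusted p = 1.5e-10), while the transcription factors Hand2 and Phox2a were at 0.33 ± 0.029 and 0.31 ± 0.037. Of 15 axon guidance genes, 10 rose and 0 fell (median 0.20, adjusted p = 8.3e-06, and adjusted p = 0.13 with an estimated correlation), with Slit1 at 0.99 ± 0.076, the netrin receptor Unc5b at 0.35 ± 0.038 and Nrp2 at 0.33 ± 0.038. Of both lists, 9 and 10 genes rose when adjusted over the list alone. Elavl4, a neuronal RNA-binding protein, was at -0.50 ± 0.031 in the list of cytoskeleton, synapse and granule genes, in which 10 rose, 6 fell and 10 did not pass (adjusted p = 0.48).

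**Figure D3:**
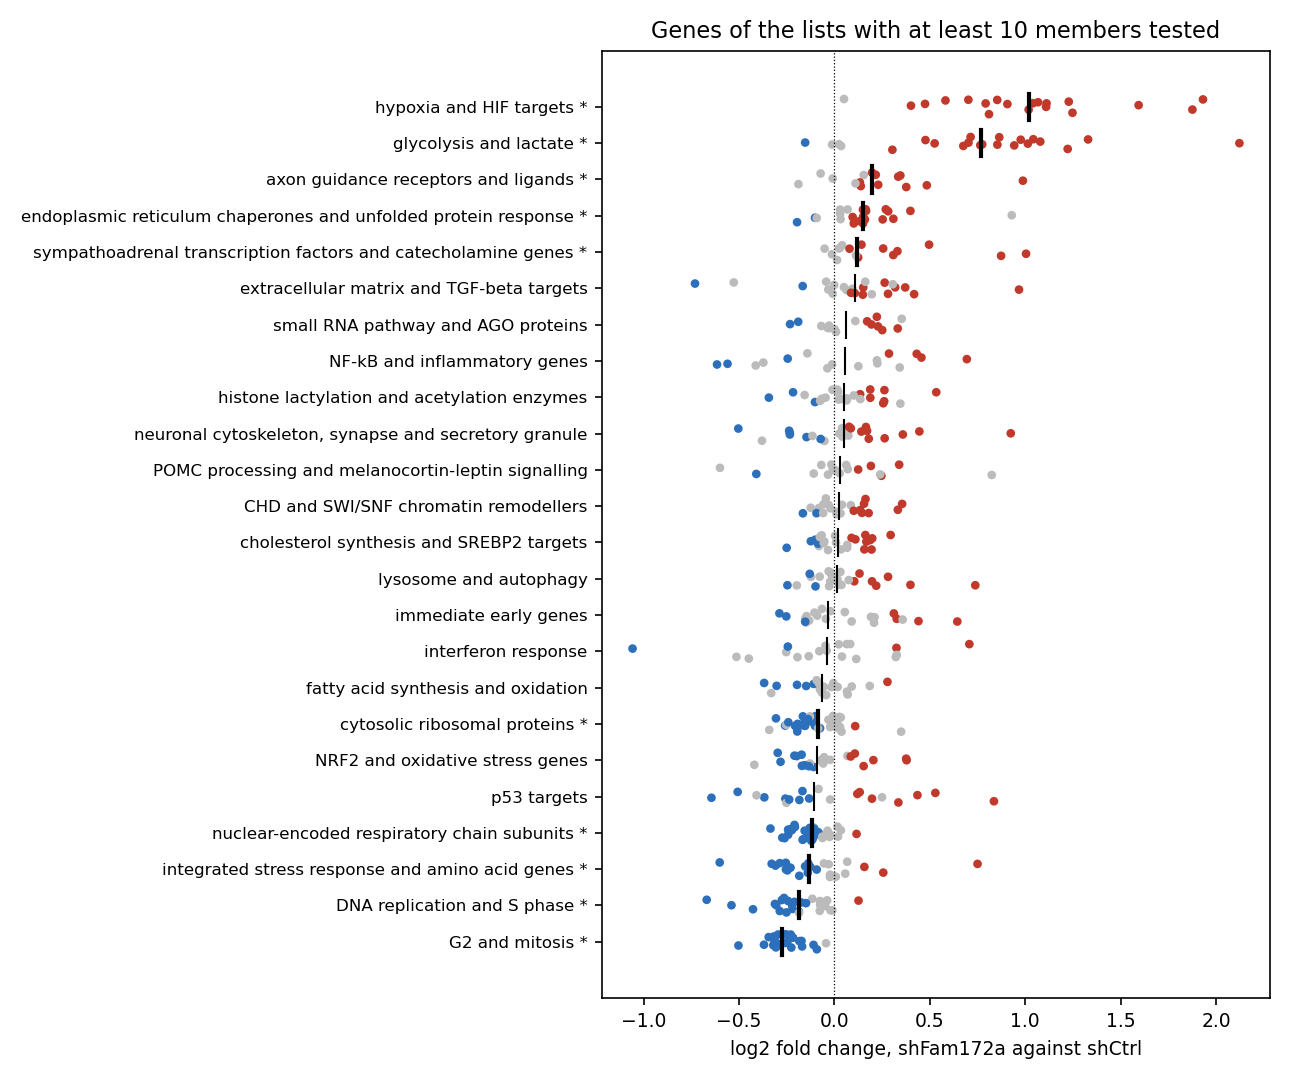
Log2 fold change of shFam172a against shCtrl for each tested gene of the lists with at least 10 tested members (red, rose; blue, fell; grey, did not pass an adjusted p of 0.05). Black bars are list medians, and an asterisk marks a list whose camera test has an adjusted p under 0.05 at the preset correlation; the hypoxia list has the highest median, 1.02, and the G2 and mitosis list the lowest, -0.27.

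The POMC and histone enzyme lists, which come from the series title, did not pass the list test. Pomc, the precursor of melanocortin peptides, was low in this line at 2.58 ± 0.40 and 2.71 ± 0.10 CPM, with 24 to 64 counts per library (0.06 ± 0.20, adjusted p = 0.85), and without shCtrl replicate 3 its sign turned (-0.05, adjusted p = 0.89). Of 17 tested genes of POMC processing and melanocortin-leptin signalling, 4 rose, 1 fell and 12 did not pass (adjusted p = 0.42). The member with the smallest p was Pam, the peptide-amidating enzyme, at 0.34 ± 0.037. The others called, chosen after their values were seen, were Insr at 0.19, Irs1 at 0.25 and Isl1 at 0.12, and Socs3 at -0.41. Of 24 enzymes of histone lactylation and acetylation, 7 rose, 3 fell and 14 did not pass (adjusted p = 0.36). Ep300, the acetyltransferase p300 that is also reported to place lactyl marks, was at 173 ± 1.15 and 181 ± 4.51 CPM (0.07 ± 0.032, adjusted p = 0.11), and after a correction for transcript length and GC it was at -0.05 with adjusted p = 0.21. Acss2, the acetyl-CoA synthetase of cytosol and nucleus, was at 0.53 ± 0.048 (adjusted p = 1.7e-11), with exons that overlap Ggt7 and Gss on the opposite strand. In the first list 4 rose and 1 fell, and in the second 7 rose and 4 fell, when adjusted over the list alone.

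Among responses that viral hairpins can set off, the interferon, NF-kB, p53 and small RNA lists did not pass the list test. The chaperone and integrated stress response lists, of the same kind, passed at the preset correlation but not with an estimated one, as given above. The test looks for a shared direction, so it does not show that a list with both rises and falls is undisturbed. Of all genes tested, 36.1% were called. Of 19 interferon response genes tested, 2 rose, 2 fell and 15 did not pass (adjusted p = 0.82); the chemokine Cxcl10 was at -1.06 ± 0.32 from 1.62 ± 0.67 to 0.774 ± 0.126 CPM, and without shCtrl replicate 1 it was at -0.72 with adjusted p = 0.16. In the NF-kB list 4 rose and 3 fell of 16 (adjusted p = 0.50), with Nfkbiz at 0.43 ± 0.053. In the p53 list 7 rose and 8 fell of 20 (adjusted p = 0.67), with Btg2, an antiproliferative gene, at 0.84 ± 0.064. Small RNA pathway and AGO genes rose in 6 and fell in 2 of 16 (adjusted p = 0.30), with Tnrc6b at 0.33 ± 0.032. Adjusted over the list alone, these lists had 0 and 1, 4 and 4, 8 and 8, and 6 and 2 genes that rose and fell.

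The remaining lists did not pass. Extracellular matrix and TGF-beta genes came nearest, with 10 of 23 higher and 2 lower (adjusted p = 0.051), and Tgfb1 was among those that fell; under 9 of 16 other settings of scaling, filter, test or libraries the list passed, with adjusted p from 0.017 to 0.20. CHD and SWI/SNF remodellers rose in 8 and fell in 2 of 22 (adjusted p = 0.36; Arid2 0.33 ± 0.032). Cholesterol genes rose in 9 and fell in 4 of 24 (adjusted p = 0.42; Stard4 0.29 ± 0.037), and fatty acid genes rose in 1 and fell in 5 of 21 (adjusted p = 0.50; Scd2 0.28 ± 0.025). NRF2 genes rose in 6 and fell in 9 of 22 (adjusted p = 0.35; the ferritin heavy chain Fth1 -0.30 ± 0.029). Lysosome and autophagy genes rose in 7 and fell in 3 of 24 (adjusted p = 0.30; the autophagy kinase Ulk1 0.74 ± 0.052). Immediate early genes rose in 4 and fell in 3 of 22 (adjusted p = 0.67; Fosl2 0.64 ± 0.054), with a median of -0.03, a mean of 0.06 and an upward test. Adjusted over the list alone, the rises and falls were 11 and 2 for matrix genes, 9 and 3 for remodellers, 9 and 4 for cholesterol, 1 and 5 for fatty acids, 6 and 11 for NRF2, 7 and 4 for lysosome, 4 and 3 for immediate early genes, and 10 and 6 for the cytoskeleton and synapse list.

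Markers of other cell types were mostly under the filter. Of 12 fibroblast markers 5 were tested, of which 1 rose (Fbln1, 0.08 ± 0.031, adjusted p = 0.035) and 0 fell. Fbln1 was not low in this line, at 293 ± 14.8 CPM in shCtrl and 311 ± 3.38 CPM in shFam172a. Of 14 macrophage markers only Cd68 was tested, at 0.514 ± 0.249 and 1.02 ± 0.107 CPM with 3 to 24 counts per library (adjusted p = 0.048). Of 16 astrocyte and oligodendrocyte markers 5 were tested and 1 fell (Cnp, -0.23 ± 0.079, adjusted p = 0.021). Cnp went from 23.8 ± 0.834 CPM in shCtrl to 20.4 ± 2.36 CPM in shFam172a. This list had a median of 0.05, a mean of -0.00056 and a downward test. Of 13 endothelial and epithelial markers 3 were tested and 0 were called. The list tests gave adjusted p = 0.87, 0.58, 0.95 and 0.82 in this order. Adjusted over the list alone, 0 fibroblast markers, Cd68, Cnp and 0 endothelial or epithelial markers were called. The calls of Fbln1, Cd68 and Cnp were lost when 4, 4 and 3 of the 6 libraries were left out one at a time, with adjusted p up to 0.34, 0.31 and 0.11.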

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

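All values in this part were chosen after the data were seen. The share of read pairs that fell in no gene was higher in every shFam172a library than in any shCtrl library, with a mean of 17.4% ± 0.388 (SD, n = 3) against 16.5% ± 0.0594. The share of pairs with several alignments was also higher in all 3 shFam172a libraries, with a mean of 10.3% ± 0.234 against 9.64% ± 0.0608. An exact two-sided permutation test gave p = 0.1 for both, the smallest that 3 against 3 libraries can give.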

How the results depend on the processing

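The thinning to equal depth and the correction for transcript length and GC were chosen after seeing the data. Fam172a was lower under all 16 other settings, with log2 fold changes from -1.13 to -1.05 and adjusted p up to 1.7e-09. Of 62 tested named genes, 55 kept direction and side of the threshold under all 16, and of 990 values 968 did, 19 lost the call, 1 gained it and 2 turned sign. DESeq2 called 1636 genes higher and 1763 lower, 3397 of them also called by edgeR; thinned libraries gave 2042 and 2085. Upper quartile scaling turned the balance to 2486 higher and 2171 lower. The balance also turned, by less, with no filter (2285 and 2274) and after the length and GC correction (2225 and 2198). After the length and GC correction 3659 of the main calls (79.1%) were called again, 4 of them in the opposite direction, and no other setting had such a gene. The count of genes at least 2-fold lower was 24 with no filter, 5 at a mean CPM of at least 1, 5 with DESeq2 and 21 with limma-voom. The first pair differ by construction in the low genes they test, and for the other tools the cause was not tested. Against a 1.5-fold change, 73 genes were higher and 1 lower. With an estimated correlation 2 lists passed, the hypoxia and glycolysis lists, which passed under all 18 settings with medians from 0.99 to 1.04 and from 0.75 to 0.79. There, G2 and mitosis had adjusted p = 0.060 and S phase 0.16, and both passed under the other 17 settings. By fry, which does not compare a list with other genes, 17 passed. The median of the ribosomal protein list, which passed in the main test, turned from -0.085 to 0.022 after the length and GC correction, where its call was lost (adjusted p = 0.82). The sign of a gene or the direction of a list test also turned for values that did not pass: Ep300 after the length and GC correction (-0.048), the remodeller list there (adjusted p = 0.53), and fibroblast markers with no filter (adjusted p = 0.91). Medians alone turned sign under at least 1 other setting for fibroblast markers (to -0.028 after the length and GC correction) and for the interferon, NF-kB, lysosome, POMC, cholesterol, immediate early, and astrocyte and oligodendrocyte lists, none of which passed in the main camera test. With each library left out in turn, Pomc ranged from -0.053 to 0.15, and the list tests had adjusted p from 0.32 to 0.98 for immediate early genes and from 0.79 to 0.95 for astrocyte and oligodendrocyte markers. The cause of these turns was not tested. With replicate number as a block (paired numbers), 2150 genes were higher and 2318 lower, no named gene or list changed its call, and deviations of libraries with the same number correlated at -0.0054, -0.0038 and -0.0096, so the numbers were not taken to pair samples. Depth limits genes such as Pomc, Cxcl10 and Cd68, with few counts in shCtrl.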

Other observations

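The 4 gene families in the first paragraph, the test of HIF subunit transcripts and the value of Hif3a were chosen after the results were seen, as were the thinning and the length and GC correction. The families are described by counts of called genes. Each was also tested by camera, and all 4 passed with the preset correlation, but they were picked for their values, so these tests are not used as evidence. With an estimated correlation the mitochondrial ribosomal proteins (adjusted p = 0.10) and the proteasome (adjusted p = 0.25) did not pass. Of 18 glycogen genes tested, 11 rose and 1 fell, with a median log2 fold change of 0.34. Gys1, glycogen synthase, was at 1.12 ± 0.038 (SE), Ppp1r3c, which targets a phosphatase to glycogen, at 1.54 ± 0.18, Pygl, a glycogen phosphorylase, at 0.63 ± 0.036, and Ugp2, which makes UDP-glucose, fell (-0.12 ± 0.034). Of 16 KDM histone demethylases, 10 rose and 0 fell (median 0.17), led by Kdm3a (0.85 ± 0.033), which is also in the hypoxia list, and Kdm4b (0.88 ± 0.048). Mitochondrial ribosomal proteins fell in 44 of 77 and rose in 0 (median -0.16), with Mrpl30 at -0.54 ± 0.044. Proteasome subunits fell in 20 of 37 and rose in 0 (median -0.11). No family median changed sign under the RLE, upper quartile or library total scalings. After the length and GC correction the medians were 0.30 for glycogen genes, 0.10 for demethylases, -0.10 for mitochondrial ribosomal proteins and -0.024 for the proteasome.

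The rise of the hypoxia and glycolysis lists was set against depth, transcript properties and culture. After all libraries were thinned to the smallest total, the hypoxia median was 101% of its value at full depth. Thinning keeps the expected share of each gene, so this value could hardly move and does not decide on depth. A batch of library making or sequencing shared by the deeper group cannot be told apart from the knockdown. After the length and GC correction the hypoxia median was 97.0% of its value, so a length or GC trend does not account for the rise of this list. The transcripts of the HIF subunits Hif1a, Epas1 and Arnt summed to 309 ± 5.39 CPM in shFam172a against 334 ± 8.51 in shCtrl (92.4%), with no overlap between groups, which argues against more transcript of these 3 as the source; protein was not measured. Nearly all of the sum is Hif1a and Arnt, as Epas1 had 0 to 2 counts per library, and a further alpha subunit left out of it, Hif3a, rose from 1.27 ± 0.375 to 2.47 ± 0.428 CPM (adjusted p = 0.0042). Wells that differed in oxygen, density or medium cannot be told apart from the knockdown, because wells and virus go together in this design. The same holds for a difference in virus dose or preparation and for other effects of either hairpin. An effect of the knockdown stays open as untested. The largest range of the hypoxia level within a group, that of shCtrl, was 24.3% of the difference between groups.

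The fall of the mitosis and S-phase lists was weighed in the same way. Over the 55 genes of both lists, the median was 102% of its value after thinning, which for the same reason does not decide on depth. After the length and GC correction the median was 89.2% of its value, so transcript properties do not account for the fall as a whole. All 25 mitosis genes and 24 of 30 S-phase genes lay below the median of the 20 genes nearest in length and GC outside the lists. The S-phase list alone lost more to the correction, with a median of -0.14 against -0.19 (adjusted p = 2.3e-08 after it), so part of its fall may follow transcript properties. An effect of the knockdown stays open as untested. The design does not separate it from wells that differed at harvest or from a library batch shared by a group. Nor does it separate it from a difference in virus dose or preparation, or from other effects of either hairpin.

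The fall of the ribosomal protein and respiratory chain lists is open to a technical source. These transcripts are short, with a median of 1052.5 bases over both lists against 3132 for all tested genes. After the correction the median over both lists was 25.5% of its value, with a bootstrap interval over genes that crosses 50%. Genes outside the lists with the nearest length and GC had a median of -0.059 against -0.10 for the lists. Short transcripts in general were thus lower, and over both lists a length trend cannot be told apart from a fall of these genes. The lists differed when taken alone. Of the ribosomal protein genes, 24 lay below and 19 above their nearest genes, and the corrected median was 0.022 (camera adjusted p = 0.82). Of the respiratory chain genes, 23 lay below and 12 above, and the corrected median was -0.043 (camera adjusted p = 0.035). Library sizes that left out the risen hypoxia and glycolysis genes kept 95.8% of the fall. The main fit was already scaled by TMM, so this value could hardly move and does not decide. The left-out genes held 1.26% to 1.33% of gene counts in the shCtrl libraries and 2.15% to 2.24% in the shFam172a libraries. So small a shift in share argues against reads taken up by those genes as the source of the fall.

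For the number of called genes, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave 4627 genes by edgeR, and the highest of the others gave 0, with up to 255 genes at an unadjusted p under 0.05. With 10 splits no share under 0.05 can be reached. Every other split puts libraries of both groups on each side, so the group difference adds to its spread and few calls can result. These splits therefore give no fair count of calls by chance.

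A hairpin can also lower other transcripts through a seed match in their 3' UTRs, and its sequence is not used here, so all words of 7 bases were tested over 12108 genes after UTR length and GC. The lowest z, -4.96, was that of ATCACAA, carried by 1092 genes with a mean log2 difference of -0.037, and the highest z of any word was 4.36. The shCtrl cells also received a hairpin, whose seed matches would appear as rises, so the highest z is no measure of noise. The lowest z of 100 permutations was -5.32, and 2 of them went as low as the real one. Overlapping words (TCACAAG, CACAAGA, AATCACA) were among the 5 lowest. ATCACAA occurs in the coding sequence of Fam172a, at 77825326 to 77825332 on chromosome 13 in exon 4 of its longest transcript, as do 20.4% of the tested words somewhere in that transcript. A seed effect of the hairpin may therefore add a small share of the falls, but at this size the test decides neither way.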
